A study of Homo sapiens with 22 samples.

How the data were processed

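The series holds 22 CUT&RUN libraries from A673 and CHLA10, 2 established Ewing sarcoma cell lines. CUT&RUN uses an antibody to direct micrococcal nuclease to chromatin, and the short fragments it releases are sequenced. Here the reaction ran on an automated platform with 250000 to 500000 cells per library, and the reads were paired-end with 25 bp at each end. Per the labels, the antibody against the homeobox transcription factor HOXD13 was used at 1:20 in 1 library per line. Antibodies against H3K4me1, H3K4me3 and H3K27me3 were used at 1:100, and those against H3K27ac and IgG at 1:50. Each histone mark was profiled in 2 libraries per line, in cells labelled shNS. The HOXD13 libraries lack that label, so overlaps of HOXD13 peaks with marks compare differently labelled cells. The 4 IgG libraries came without peak lists and entered no comparison. Whether replicates came from separate cultures is not stated.

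The authors deposited 18 peak lists, 1 per library, and peaks were called per sample, not on pooled replicates. Bowtie2, MACS2, SEACR 1.2, bedtools and the build hg38 are named in the submitters' processing notes, without the role of each. Peak names in the deposited lists place the HOXD13, H3K27ac, H3K4me1 and H3K4me3 calls in a comparison with IgG, as narrow peaks. H3K27me3 was called as broad peaks without a control, and its shortest deposited peak is 2000 bp long. In every list the authors give a fold enrichment of the peak (a ratio over the caller's background). The authors also give −log10 p and −log10 q values per peak, and a score that was checked to be the −log10 q value multiplied by 10 and cut to a whole number. No deposited peak has a q-value above 0.01. Peak numbers in the deposited lists have gaps, so each list is a subset of a longer one. The lists kept between 1.00% (CHLA10 HOXD13) and 77.2% (CHLA10 H3K4me3 replicate 1) of the highest peak number. The criterion behind the gaps is not stated, so a comparison between lists carries any difference in that selection. The lists hold no read counts, and the read depth behind a peak is unknown.

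Peaks on chromosomes 1 to 22 and X were used. Chromosome Y and XIST were left out, and peaks on unplaced sequences were only counted. Genes came from the RefSeq annotation of the same build, with 19974 protein-coding genes on these chromosomes. That annotation gave gene boundaries without strand or exons. The planned promoter, a window around the transcription start, was therefore replaced by a window of 1 kb on each side of both gene boundaries, called the gene ends below. Exons and introns were not told apart for the same reason. The planned search for HOX and GGAA-repeat motifs under HOXD13 peaks needed a genome sequence and was not run. Random placements were planned along whole chromosomes and were restricted to 100-kb bins of the same chromosome that hold a peak of any list (2772 Mb), which keeps them out of unmappable sequence.

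A gene end carried a mark in a library when a peak overlapped its window by at least 1 bp. A gene counted as marked in 1 line only when both libraries of that line and neither library of the other had such a peak. With 2 libraries against 2 there are 3 splits, and an exact permutation test cannot go below p = 0.33, so no p-value was computed between lines. The same count was taken instead for the 2 mixed splits, which pair a library of one line with a library of the other. H3K27ac peaks of the 4 libraries were merged, and merged regions over 2.5 kb from every gene boundary were compared in the same way.

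HOXD13 peaks were compared between lines and with each mark by overlap of at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. They were set beside 1000 random placements. A HOXD13 peak was assigned to the nearest gene boundary within 100 kb. For marks at HOXD13 peaks, values are the mean and SD over the 2 libraries of the mark.

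Before the data were examined, 17 gene lists with 540 genes were fixed from textbook knowledge of Ewing sarcoma, HOX biology, cell lineages and pathways, together with the alternatives and the rule for named genes. Of these genes, 538 were measured; GPR64 and LOR were not found under these symbols. For each list, mark and line, the count of members marked in that line only was compared with 10000 random lists of the same size, drawn from genes marked in at least 1 of the 4 libraries. HOXD13 counts were compared with 10000 random lists matched on deciles of the distance to neighbouring genes. For the alternative of a peak inside the gene or within 10 kb, the lists were matched on deciles of gene length instead. There 1 peak could count for several neighbouring genes. The one-sided permutation p-values were adjusted by Benjamini-Hochberg over 136 combinations for the marks and 34 for HOXD13. Genes are not replicates and neighbours share peaks, so these p-values describe the lists in these libraries and do not test a difference between lines.

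The rule for named genes took the genes nearest the 10 HOXD13 peaks with the highest −log10 q in each line, and list members with a HOXD13 peak shared by both lines. For each mark and direction it took the 5 genes, and for distal H3K27ac the 5 regions, with the highest rank. The rank is the lower of the percentile ranks, by −log10 q, of the peak in its own 2 lists. All HOX cluster genes were also taken, and 2 to 4 members of each list by the same rank. A gene named outside this rule is said to have been picked after its values were seen. Some genes taken by this rule are not reported here.

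The alternatives were an overlap of at least 50% of the smaller peak, the upper 50% of each list by q, lists of equal peak number, windows of 500 bp and 2.5 kb, a distance of 1 kb for distal regions, all annotated genes, a mark peak in both or in either replicate, a HOXD13 peak inside the gene or within 10 kb, and leaving out each replicate in turn. Chosen after seeing the data were the use of only the boundary with more H3K4me3 libraries, the removal of genes in long stretches free of peaks, and leaving out replicates for the gene lists. The overlap and gene-end code was tested on simulated data, and all planted overlaps and all planted line-only genes were recovered (100.0%). Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.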

Results

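HOXD13, a homeobox transcription factor of posterior development, and 4 histone marks were mapped by CUT&RUN in A673 and CHLA10, established lines of Ewing sarcoma, a bone and soft tissue tumour driven by the EWS-FLI1 fusion. The series title places HOXD13 and EWS-FLI1 in the control of tumour cell plasticity. Of 22 libraries, 2 were against HOXD13 (1 per line), 16 against histone marks (2 per mark and line) and 4 against IgG. H3K4me3 marks active or poised promoters, H3K27ac active promoters and enhancers, H3K4me1 enhancers, and H3K27me3 chromatin held by Polycomb repressors. The HOXD13 lists held 7160 peaks in A673 and 2099 in CHLA10, with median lengths of 192 and 349 bp. Histone lists ranged from 17909 peaks (A673 H3K4me3 replicate 1) to 106770 peaks (A673 H3K4me1 replicate 1). The lists give peaks and no read counts, so the depth behind each peak is unknown, and every share below counts called peaks.

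How well replicates repeated each other set how far a difference between lines could be read. H3K4me3 repeated best, with 90.7% of the shorter A673 list and 83.8% of the shorter CHLA10 list found in the other replicate. H3K27me3 repeated at 80.7% and 69.9%. H3K27ac differed by line, with 23.4% in A673 (95% interval 23.01 to 23.84) against 71.9% in CHLA10 (71.3 to 72.4). H3K4me1 went the other way, with 64.8% in A673 and 25.3% in CHLA10. Of CHLA10 H3K4me1 replicate 1 peaks, 22.9% were in the other replicate, but 32.1% and 25.5% in the longer A673 lists. Of A673 H3K27ac replicate 1 peaks, 19.1% and 15.2% were in the CHLA10 lists. Replicates thus repeated little or no better than the lines did in both cases. CHLA10 H3K27ac replicate 2 and A673 H3K4me1 replicate 2 overlapped the other line at most at 24.9% and 13.4%, well below their repeat.

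The first comparison asked where HOXD13 sits in each line and whether the sites are the same. Most HOXD13 peaks were called in 1 line. In A673, 517 of 7160 peaks (7.22%, 95% interval 6.63 to 7.84) overlapped a CHLA10 peak, and in CHLA10, 504 of 2099 (24.0%, 22.2 to 25.9) overlapped an A673 peak. Random placement gave 0.0461% and 0.159%, so the shared part was 156 and 151 times the random level. Sharing was higher among the 10% of A673 peaks with the highest −log10 q (14.8%), and in CHLA10 those 10% shared 27.6%. At the gene level, 3260 genes in A673 and 971 in CHLA10 had an assigned peak, and 563 had one in both, where independence would give 158. That number treats every gene as equally likely to have a peak and ignores the distance to neighbouring genes, so part of the excess may follow from gene spacing.

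The strongest HOXD13 peak of both lines lay at RNF181, an E3 ubiquitin ligase gene, and touched the gene in A673 (chromosome 2, 85595481 to 85595773, −log10 q 996.5, fold enrichment 58.3). The CHLA10 peak at the same place had a −log10 q of 654.8. HLA-DMB, which encodes a chaperone of peptide loading on class II HLA molecules, came second in both lines (chromosome 6, −log10 q 269 in A673 and 329 in CHLA10). Next in A673 were peaks inside VMP1, an autophagy gene, and AUTS2, a gene of neuronal development, and peaks near the dopamine receptor gene DRD1 and the growth regulator gene FJX1. MACF1, which links microtubules to actin, held a peak, and the atypical cadherin gene FAT3 was the nearest gene to another, 352 kb away. Those 6 peaks and one inside the GTPase-activating protein gene ARHGAP10 overlapped a CHLA10 peak, whereas the peak inside ARHGAP26, a gene of the same family, did not. In CHLA10 the third peak lay inside CRB1, a cell polarity gene of the retina (−log10 q 313), and had no A673 counterpart. MEIS1 encodes a homeodomain partner of HOX proteins, and the peak nearest to it, 443 kb away (−log10 q 241), was shared with A673. Peaks inside PNISR and the exocyst gene EXOC4 were shared too. The CHLA10 peak nearest GRIK2, a glutamate receptor gene, was called in CHLA10 only, as were those inside OTOGL and PPTC7.

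Among members of the fixed lists, 7 genes had a HOXD13 peak at the same place in both lines. They were CCN1, a secreted matrix-associated protein gene, the collagen genes COL3A1 and COL11A1, the cell cycle kinase gene CDK1, the transcription factor genes FOXO1 and PAX3, and KDSR, a gene of sphingolipid synthesis. The CCN1 peak lay 0.457 kb from the gene (A673 −log10 q 13.6, CHLA10 17.3) and carried H3K27ac in both CHLA10 libraries and in neither A673 library. At COL3A1 the shared peak lay inside the gene, 2.17 kb from its boundary (14.4 and 15.9). PAX3 had 2 shared peaks, 78.7 and 81.7 kb away. At the HOXD cluster itself, A673 had a peak 1.79 kb from HOXD12 (chromosome 2, 176104283 to 176104471, −log10 q 24.3) that CHLA10 lacked. CHLA10 had a peak inside the neighbouring gene MTX2 (176278787 to 176279228, −log10 q 64.1) that A673 lacked. A second MTX2 peak was called in both (17.7 in A673 and 4.66 in CHLA10).

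**Figure D1:**
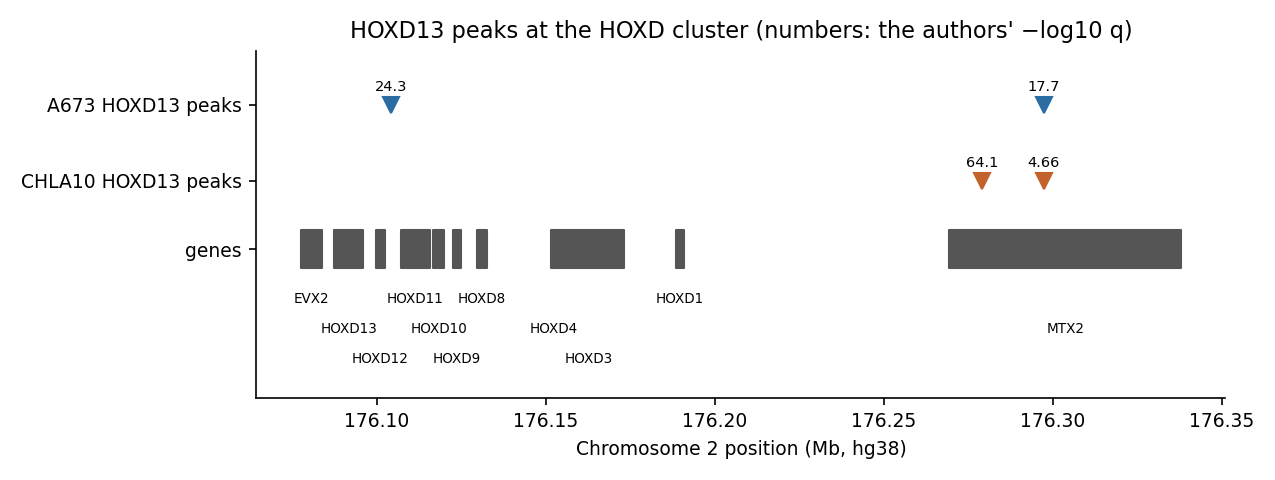
HOXD13 peaks (triangles, blue for A673 and orange for CHLA10) over the HOXD cluster and MTX2 on chromosome 2, in Mb of hg38, with the authors' −log10 q above each triangle and genes as grey bars. The A673 peak near HOXD12 (24.3) and the stronger CHLA10 peak in MTX2 (64.1) were each called in 1 line, and the second MTX2 peak in both.

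HOXD13 peaks lay mostly away from gene boundaries. Within 1 kb of a boundary were 5.84% of A673 peaks (5.31 to 6.41), against 2.79% for random placement. In CHLA10 the share was 2.81% (2.15 to 3.61), against 2.94% for random placement. Inside genes lay 47.0% and 45.7%, and between genes 47.2% and 51.5%.

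HOXD13 peaks overlapped H3K27ac more often in CHLA10 and H3K4me1 more often in A673, but set against random placement the H3K4me1 gap nearly closed. The mark libraries came from cells labelled shNS, a label that the HOXD13 libraries lack. H3K27ac covered 47.4% ± 4.28 (SD, n = 2 libraries of the mark) of CHLA10 HOXD13 peaks, 33.4 times the random level, and 16.7% ± 2.56 (n = 2) of A673 peaks, 13.4 times the random level. For H3K4me1 the shares were 35.9% ± 4.83 in A673 and 8.004% ± 0.606 in CHLA10 (n = 2 each), 12.1 and 10.96 times the random level. The A673 H3K4me1 lists cover 74.5 and 51.6 Mb, those of CHLA10 9.63 and 11.3 Mb. H3K4me3 covered similar shares, 8.88% ± 0.188 in A673 and 9.22% ± 0.303 in CHLA10 (n = 2 each), 6.05 and 5.76 times the random level. H3K27me3 was rarer at HOXD13 peaks than at random places, with 3.41% ± 0.662 in A673 and 0.381% ± 0.135 in CHLA10 (n = 2 each), 0.524 and 0.0487 times the random level. Peaks with H3K27ac in both replicates and H3K4me3 in neither, the marks of distal enhancers, made up 7.85% in A673 and 28.8% in CHLA10, a contrast that carries the lower repeat of H3K27ac between A673 replicates (23.4% against 71.9%), and 39.7% and 35.9% carried none of the 4 marks in any replicate. A673 HOXD13 peaks overlapped H3K27ac of CHLA10 (24.3% ± 3.47, n = 2) more often than H3K27ac of A673 itself. The same held for A673 H3K4me3 replicate 1 peaks, so this order was not particular to HOXD13 sites. The 2 CHLA10 H3K27ac libraries covered 36.6% and 25.2% of those H3K4me3 peaks, and the 2 A673 libraries 18.2% and 19.4%. Among the A673 peaks shared with CHLA10, 46.8% ± 0.821 (n = 2) carried CHLA10 H3K27ac. The H3K27ac and H3K4me1 differences in share between lines exceeded the SDs, but 2 against 2 libraries of a mark allow no test below p = 0.33 by exact permutation. The SDs cover the mark libraries only. Each share also rests on a single HOXD13 library, whose spread is unknown. Requiring a peak in both libraries of the mark lowered H3K27ac in A673 to 9.66% and H3K4me1 in CHLA10 to 2.81%, and the upper 50% of each list by q lowered H3K4me3 to 3.92% and 2.43%.

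**Figure D2:**
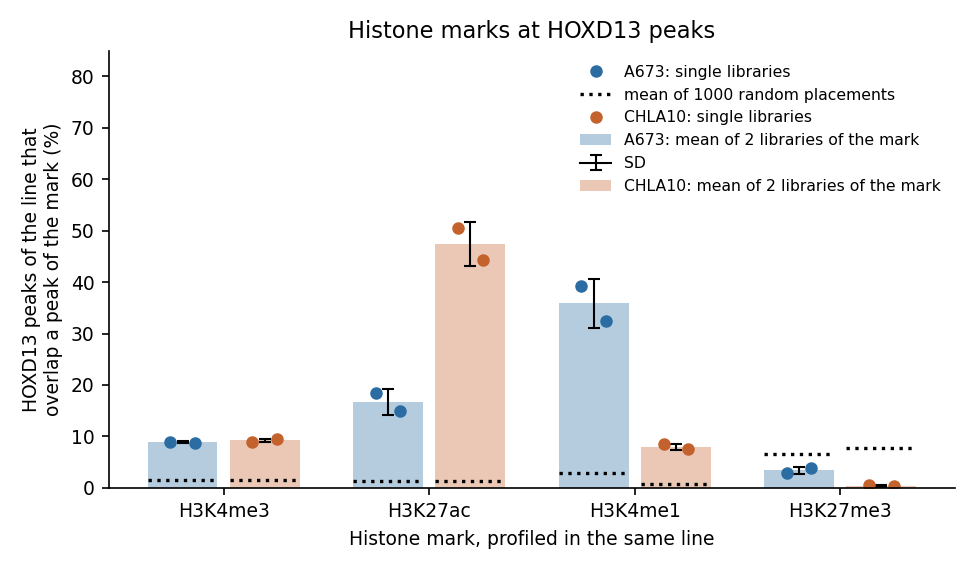
Share of HOXD13 peaks (percent) that overlap a peak of each histone mark in the same line, as single libraries (points), their mean (bars) and SD (n = 2 libraries of the mark), with the mean of 1000 random placements as dotted lines. H3K27ac covers 47.4% of CHLA10 and 16.7% of A673 peaks, H3K4me1 35.9% of A673 and 8.004% of CHLA10 peaks, and H3K27me3 lies under the dotted line in both.

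Genes known to be repressed by EWS-FLI1 stood out near A673 HOXD13 peaks. Of 32 such genes, 17 were nearest to a peak, where random lists gave 8.18 (permutation p = 0.00060, adjusted permutation p = 0.0204 over 34 combinations). The members with the strongest peaks were TGFBI, a matrix protein gene induced by TGF-beta (53.4, the authors' −log10 q), ANXA1, an annexin gene (33.2), THBS1, the thrombospondin 1 gene (32.9), and INHBA, an activin subunit gene (28.5). In CHLA10, 5 of the 32 had a peak, with 2.66 expected (adjusted permutation p = 0.666). They were CCN1, FOXO1, COL5A2, CALD1 and ANXA1, and all 5 had a peak in A673 too. Whether the lists differed between lines was not tested. The A673 call did not hold with the upper 50% of each list by q (12 genes, 5.02 expected, adjusted permutation p = 0.0748) or with lists of equal peak number (7 genes, 3.24 expected, adjusted permutation p = 0.394). The counts were smaller there, while the ratio to the expected number was 2.39 and 2.16, against 2.08 with all peaks. Over all 3 alternatives the adjusted permutation p ranged from 0.0034 to 0.394.

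No other list passed the adjusted threshold, and 4 came next in A673, each with an adjusted permutation p of 0.201. Of 50 mesenchymal genes, 21 had a peak (13.7 expected), led by the microfibril gene FBN1 (57.9), TGFBI, COL3A1 (42.2) and INHBA; the list shares 16 members with the EWS-FLI1 repressed list. Genes activated by EWS-FLI1 had 14 of 35 (8.42 expected), among them LIPI (50.0), IL1RAP (36.0), the kinase gene PRKCB (33.2) and the neuropeptide receptor gene NPY5R (26.4). TGF-beta and BMP pathway genes had 15 of 33 (9.58 expected), led by the receptor gene BMPR1A (66.8) and the BMP target gene ID3 (37.9). HOX genes had 5 of 39 (1.75 expected): HOXC5 (66.0), HOXC4 (56.1), HOXD12, HOXC6 and HOXB13. With a peak inside the gene or within 10 kb, HOX (8, adjusted permutation p = 0.0204), mesenchymal (17, 0.0408) and EWS-FLI1 activated genes (13, 0.0119) passed in A673. In that alternative the random lists were matched on gene length, and 1 peak could count for several neighbours. The 8 HOX genes are therefore not separate hits. Over the 3 alternatives the adjusted permutation p ranged from 0.0204 to 0.556 for HOX, 0.0408 to 1.00 for mesenchymal and 0.0119 to 0.878 for activated genes.

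In CHLA10 the counts were small: 7 mesenchymal genes (4.58 expected), among them ITGB1 (33.6) and TWIST1 (29.6), 2 EWS-FLI1 activated genes (2.68 expected; JAK1 and KDSR), 4 TGF-beta and BMP pathway genes (3.195 expected) and 1 HOX gene, HOXC11. WNT pathway genes had 11 of 38 in A673 (9.24 expected), led by the R-spondin genes RSPO2 (63.5) and RSPO3 (41.9), and 4 in CHLA10 (2.91 expected), including the stem cell receptor gene LGR5 (42.2). Developmental transcription factor genes had 21 of 83 in A673 (20.3 expected; PAX5, GBX2, HAND1) and 3 in CHLA10 (6.46 expected; among them SIM1 and ALX1). Neural genes had 8 of 30 in A673 (7.11 expected; PAX6, SOX11) and 1 in CHLA10 (2.28 expected; NEUROD1). Neural crest genes had 5 of 21 (5.77 expected; EDNRB, PAX3) and 2 (1.91 expected; TWIST1, PAX3). Chondrogenic and osteogenic genes had 7 of 24 (5.24 expected; COL11A1, SOX6) and 1 (1.66 expected; COL11A1). Cell cycle genes had 4 of 34 (4.21 expected) and 1, CDK1 (1.14 expected). Endothelial genes had 4 of 19 (4.13 expected; FLT1, KDR) and 0 (1.35 expected). Epithelial genes had 1 of 24, CDH3 (3.99 expected), and 0 (1.17 expected). Haematopoietic genes had 1 of 20 (2.26 expected) and 1 (0.665 expected), PTPRC in both lines. Myogenic genes had 0 of 16 (1.22 expected) and 1, MYH3 (0.253 expected). Housekeeping genes had 2 of 30 (2.97 expected) and 0 (0.789 expected), and genes silent in most tissues 2 of 39 (3.85 expected) and 1 (0.986 expected). The lowest adjusted permutation p among these was 0.804.

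**Figure D3:**
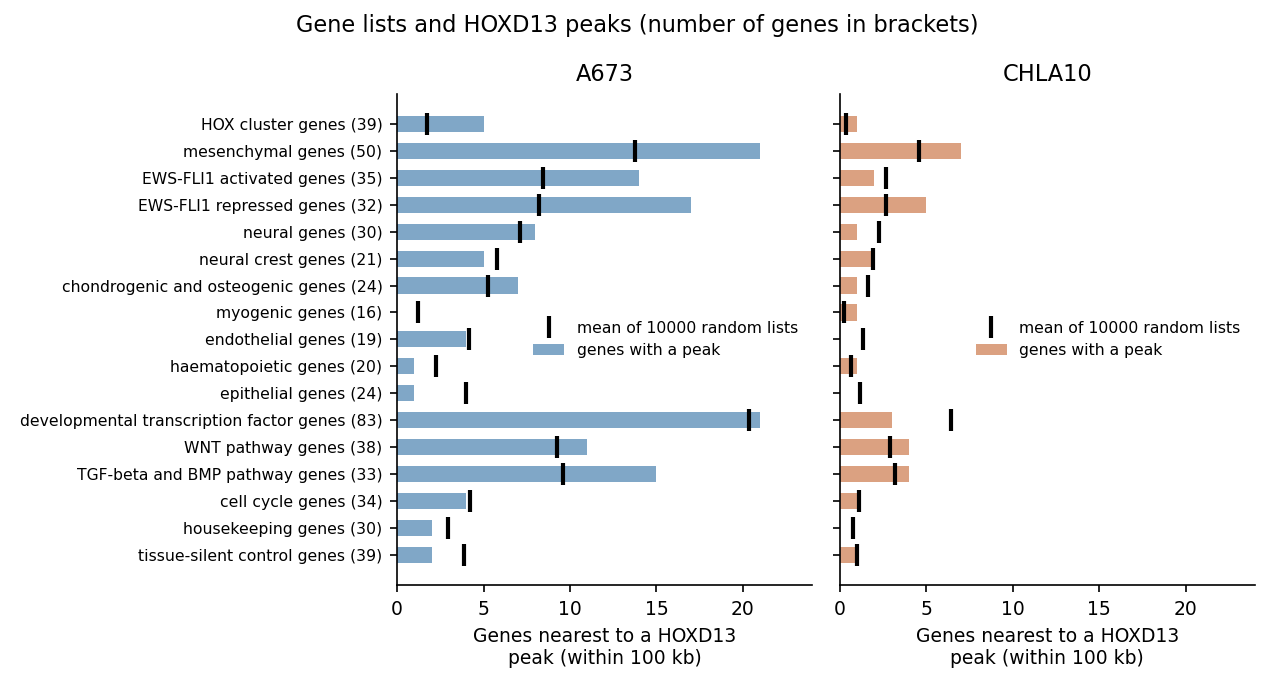
Number of genes of each fixed list that are nearest to a HOXD13 peak within 100 kb (bars) in A673 (left) and CHLA10 (right), with the mean of 10000 random lists matched on the distance to neighbouring genes (black ticks) and the list size in brackets. EWS-FLI1 repressed genes reach 17 against 8.18 expected in A673.

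The second comparison asked which gene ends carry a mark in 1 line only. For H3K4me3 the lines differed at few genes and about equally in both directions, with 391 genes marked in A673 only and 396 in CHLA10 only, beside 12224 genes marked in all 4 libraries. Single mixed pairs of libraries gave 9 to 22. Highest by rank in A673 were TMEM233 (chromosome 12, 119593774 to 119654295), FEV, an ETS factor gene of serotonergic neurons, BMP7, a bone morphogenetic protein gene, RUBCNL, an autophagy gene, and LOC107987020. At TMEM233 and FEV both CHLA10 libraries and no A673 library had H3K27me3, and at BMP7 and LOC107987020 all 4 libraries had it. In CHLA10 they were PAICS, a purine synthesis gene (chromosome 4, 56410507 to 56464578), HSPA12A, ZNF667, LOC124900173 and EVX2, the homeobox gene beside HOXD13. EVX2 carried H3K27me3 in both A673 libraries and H3K27ac in both CHLA10 libraries. LOC124900173 lies in a stretch of at least 300 kb without any A673 peak. With the upper 50% of each list by q, the CHLA10-only count was 1323, and with lists of equal peak number the ratio of CHLA10-only to A673-only genes turned from 1.01 to 0.658.

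H3K27me3 differed at more genes, with 770 in A673 only and 602 in CHLA10 only, against 14 to 51 for single mixed pairs. In A673 the top genes were HAND1, a transcription factor gene of heart development (chromosome 5, 154474972 to 154478227), FAM120B beside the Notch ligand gene DLL1, BBOX1, a carnitine synthesis gene, TMEM132B, and HOXA10. In CHLA10 they were GATA4, a transcription factor gene of heart and endoderm (chromosome 8, 11676935 to 11760002), SHOX, a homeobox gene of limb growth, and LOC101929601, LOC101929627 and LOC124902048, neighbours on chromosome 8 whose end peaks have the same rank in replicate 1. GATA4 carried H3K4me1 in both A673 libraries. With all annotated genes the counts were 2118 and 2130, so the direction of the small difference between them turned.

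Far more gene ends had H3K27ac in CHLA10 only (1678) than in A673 only (446). SUGP1, a splicing factor gene, and its neighbour MAU2, a cohesin loader gene, shared one strong A673 peak (chromosome 19, SUGP1 at 19276033 to 19320509). The neurotrophin gene NTF4, the potassium channel gene KCNA7 and the secretory GTPase gene RAB3D followed. CHLA10 had TP53BP2, which encodes a p53-binding protein (chromosome 1, 223779893 to 223845947), the tRNA splicing gene TSEN15, the cytokine gene IL17B, the myosin light chain gene MYL12B and the centriole gene CEP83. Of these 10 genes, SUGP1, MAU2, RAB3D, TP53BP2, TSEN15, MYL12B and CEP83 carried H3K4me3 in all 4 libraries of that mark. Single mixed pairs gave 81 to 345, so the A673-only count was only somewhat above the largest of them. Counting 1 library for a line in place of both changed these numbers: A673-only and CHLA10-only genes came to 1667 and 2210 without A673 replicate 1, 1428 and 2222 without A673 replicate 2, 689 and 2085 without CHLA10 replicate 1, and 502 and 3395 without CHLA10 replicate 2.

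H3K4me1 ran in the opposite direction, with 1536 genes in A673 only and 52 in CHLA10 only. HOXB3 ranked first in A673 (chromosome 17, 48548870 to 48590241), and UTP11, a ribosome assembly gene, C11orf91, the sugar metabolism gene GMPPA and its neighbour ASIC4, an ion channel family gene, followed. CHLA10 had HLCS, the gene of the enzyme that attaches biotin (chromosome 21, 36748625 to 36990211), GBP6, BABAM2, ELP3 and HSPB2, and all 5 also had H3K27ac in both CHLA10 libraries. Single mixed pairs gave 34 to 129, so the 52 CHLA10-only genes lay within that range. Without A673 replicate 2 the A673-only count was 4492 and without A673 replicate 1 the CHLA10-only count was 107; without CHLA10 replicate 1 or 2 that count was 253 or 308. Lists of equal peak number gave 590 and 113, and windows of 500 bp and 2.5 kb gave 985 and 3012 genes in A673 only.

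**Figure D4:**
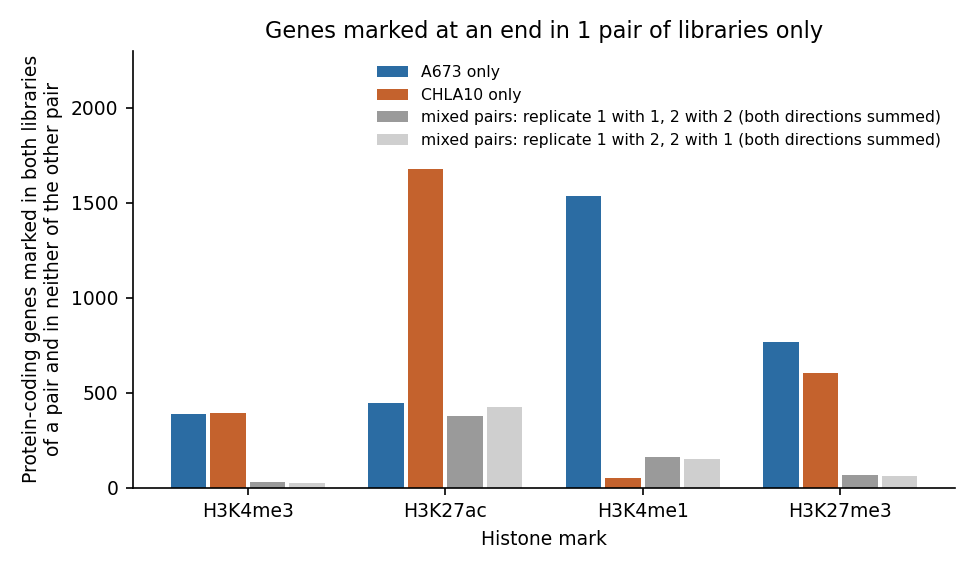
Number of protein-coding genes whose ends carry a mark in both libraries of one line and neither of the other (blue for A673, orange for CHLA10), and the same count for the 2 mixed splits of the 4 libraries (grey, both directions summed). For H3K4me3 and H3K27me3 both directions stand above the mixed splits, H3K27ac is mostly CHLA10 only (1678 against 446), and H3K4me1 mostly A673 only (1536 against 52).

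Active marks in A673 only coincided more often than independence would give, and in CHLA10 the pairs went both ways. The expected numbers treat every gene as equally likely to carry a mark. Part of an excess or a deficit may therefore follow from which genes carry these marks at all. H3K27ac in A673 only coincided with H3K4me1 in A673 only at 149 genes (34.3 expected from independence) and with H3K4me3 in A673 only at 35 (8.73 expected). In CHLA10, H3K27ac coincided with H3K4me3 at 24 genes (33.3 expected). H3K27ac with H3K4me1 at 14 (4.37 expected) and H3K4me3 with H3K4me1 at 4 (1.03 expected) rest on the 52 CHLA10-only H3K4me1 genes, a count within the range of mixed pairs. H3K27me3 and H3K27ac seldom changed at the same gene in either direction: 22 genes had H3K27me3 in A673 only and H3K27ac in CHLA10 only (64.7 expected), and 10 the reverse (13.4 expected). Both marks were in A673 only at 8 genes (17.2 expected) and in CHLA10 only at 4 (50.6 expected). For exchange with H3K4me3 the counts were 19 (15.3 expected) and 18 (11.8 expected). Beside EVX2, FEV and TMEM233, genes picked after their values were seen include DCN, a matrix proteoglycan gene, and FOXA1 and MEIS2, transcription factor genes, with H3K27me3 in A673 only. SOX1, SALL1 and SALL3, developmental transcription factor genes, had H3K27me3 in CHLA10 only and H3K4me3 in A673 only.

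Genes with H3K4me3 at an end carried H3K27ac at an end more often in CHLA10 than in A673. The shares were 45.3% and 30.9% in the 2 CHLA10 libraries and 21.02% and 22.97% in the 2 A673 libraries. Genes with both H3K4me3 and H3K27me3 in both replicates, called bivalent below, numbered 1122 in A673 and 599 in CHLA10. The 2 marks may lie at different boundaries of a gene, and both lay at one boundary in 994 and 456 of these genes. Genes with H3K27me3 alone numbered 1124 and 1437, those with H3K4me3 alone 11384 and 11835, and those with neither 5106 and 4716. Of the bivalent A673 genes, 368 were bivalent in CHLA10 too (33.6 expected from independence) and 408 had H3K4me3 alone there (665 expected), while 88 genes went the other way (341 expected). Here too the expected numbers treat every gene as equally likely to be in each state. Part of the gaps may follow from which genes carry these marks at all. With the upper 50% of each list by q the bivalent counts were 215 and 69.

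The fixed gene lists described these differences by function, and none passed the adjusted threshold for any mark. Mesenchymal genes carried H3K27ac in both replicates at 2 of 50 genes in A673 and 17 in CHLA10. Of these, 9 were marked in CHLA10 only (5.16 expected, permutation p = 0.0592, adjusted permutation p = 0.639), led by the collagen crosslinking enzyme gene LOX, the matrix gene SPARC and the integrin gene ITGAV. H3K27me3 lay at 9 mesenchymal genes in A673 and 4 in CHLA10. In A673 only were 5 (1.57 expected, permutation p = 0.0125, adjusted permutation p = 0.235): PRRX1 and ZEB1, transcription factor genes of mesenchyme, and COL6A3, DCN and FAP. Housekeeping genes showed the same direction of H3K27ac, with 5 of 30 in A673 and 17 in CHLA10. Among them 8 were CHLA10 only (4.09 expected, adjusted permutation p = 0.528), including TFRC, EIF4A2 and PSMB4.

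For H3K4me3 in A673 only, the developmental and neural lists missed the adjusted threshold. Of 83 developmental transcription factor genes, 7 had it in A673 only (1.75 expected, permutation p = 0.0021, adjusted permutation p = 0.143), led by NKX2-5, HMX3, PRDM13 and GBX2, and 2 in CHLA10 only (1.77 expected), while 13 had H3K27me3 in A673 only (10.2 expected, adjusted permutation p = 0.854). Neural genes had 4 of 30 in A673 only (0.706 expected, adjusted permutation p = 0.163), OTX2, STMN2, SOX1 and NES, and 1 in CHLA10 only (0.715 expected). The developmental list passed with the upper 50% of each list by q (12 genes, adjusted permutation p = 0.0136), without A673 replicate 2 (10 genes, adjusted permutation p = 0.0340) and without CHLA10 replicate 1 (9 genes, adjusted permutation p = 0.0476). The neural list passed without CHLA10 replicate 1 (6 genes, adjusted permutation p = 0.0476). Over the 8 alternatives the adjusted permutation p ranged from 0.0136 to 0.172 for the developmental list and from 0.0476 to 1.00 for the neural list.

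Haematopoietic genes had 3 of 20 with H3K4me3 in CHLA10 only (0.194 expected, adjusted permutation p = 0.136), namely SPI1, TAL1 and CD14, and 3 with H3K27ac in A673 only (adjusted permutation p = 0.163), namely CD79A, LYL1 and CSF1R. Chondrogenic and osteogenic genes had 3 of 24 with H3K27ac in A673 only (0.426 expected, adjusted permutation p = 0.171), RUNX2, SOX9 and SP7, the skeletal transcription factor genes. Endothelial genes had 2 of 19 with H3K4me3 in A673 only (adjusted permutation p = 0.343), EMCN and ESAM. Epithelial genes had 2 of 24 with H3K4me3 in CHLA10 only (adjusted permutation p = 0.590), EPCAM and MAL2. WNT pathway genes had 4 of 38 with H3K4me3 in A673 only (adjusted permutation p = 0.235), WNT3A, WNT7A, NOTUM and WNT10A. TGF-beta and BMP pathway genes had 2 of 33, BMP7 and BMP5 (adjusted permutation p = 0.868). Genes activated by EWS-FLI1 carried H3K4me3 at 33 of 35 in A673 and 32 in CHLA10, and 6 had H3K27ac in CHLA10 only (4.09 expected, adjusted permutation p = 0.854), led by CAV1, NR0B1, EZH2 and VRK1. Those repressed by EWS-FLI1 had 7 of 32 with H3K4me1 in A673 only (4.25 expected, adjusted permutation p = 0.700), among them CDKN1A, PHLDA1 and CCN1. Neural crest genes had 3 of 21 with H3K27me3 in A673 only (1.39 expected, adjusted permutation p = 0.716; MSX2, ETS1, MITF). The lowest adjusted permutation p was 0.642 for myogenic genes (MYOD1, H3K4me3 in A673 only) and 0.642 for genes silent in most tissues (APOA1). Cell cycle genes had H3K4me3 at 31 of 34 in A673 and 33 in CHLA10, and CDKN2A and CDKN2B, the cell cycle inhibitor genes in a stretch without any A673 peak, made up the CHLA10-only pair (adjusted permutation p = 0.872).

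The HOX clusters differed between lines in both active and repressive marks. H3K27me3 covered all 11 HOXA genes in A673 and 8 in CHLA10, and the 3 posterior genes HOXA10, HOXA11 and HOXA13 carried it in A673 only. HOXD1 had it in A673 only as well, and no HOXC gene had it in either line. H3K27ac in CHLA10 only lay at HOXB2, HOXB6, HOXB13, HOXD12 and at HOXC4, HOXC5 and HOXC6, which share one annotated boundary. HOXB3 and HOXD8 had H3K27ac in A673 only. H3K4me3 was in A673 only at HOXD10 and in CHLA10 only at HOXC12. H3K4me1 was in A673 only at HOXB2, HOXB3, HOXB9, HOXC8, HOXC10, HOXC11 and HOXD8. The HOXD13 gene (chromosome 2, 176087487 to 176095944) carried H3K4me3 in all 4 libraries, H3K27ac in both CHLA10 libraries and 1 A673 library, and H3K27me3 in 1 A673 library. As a list, HOX genes passed for no mark, with 7 of 39 for H3K27ac in CHLA10 only (4.26 expected, adjusted permutation p = 0.710) and 4 for H3K27me3 in A673 only (2.63 expected, adjusted permutation p = 0.890). These genes are neighbours that share peaks.

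**Figure D5:**
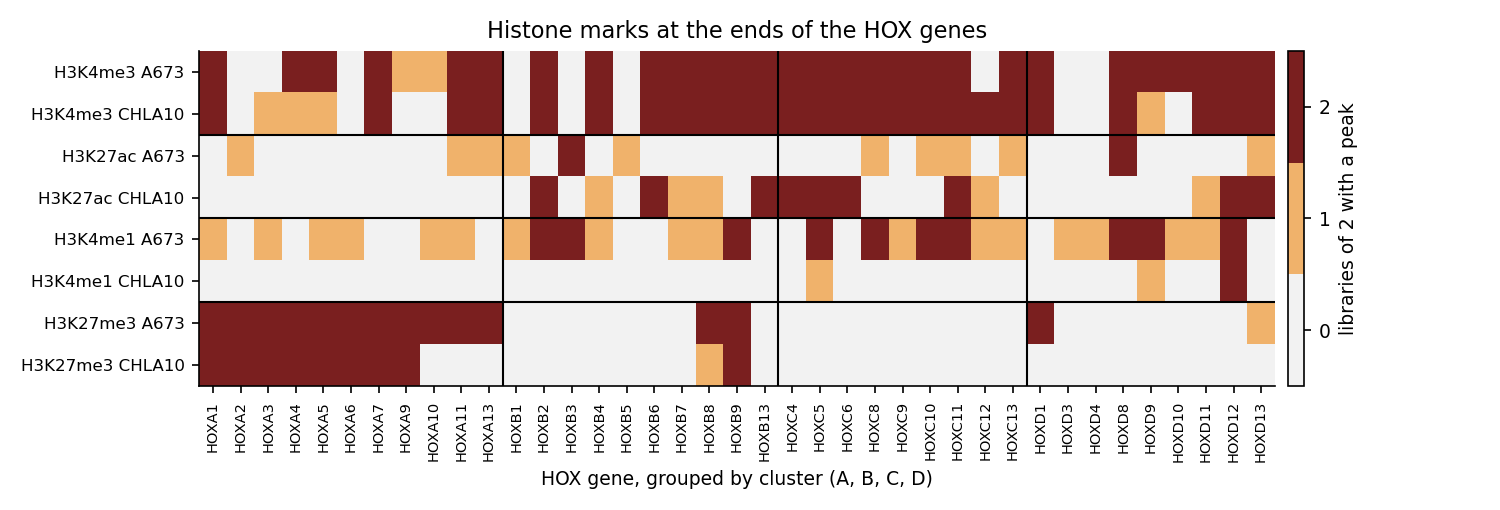
Number of libraries (0, 1 or 2) with a peak of each mark at the ends of each HOX gene, by line, with genes ordered along clusters A to D. H3K27me3 covers the HOXA cluster, with HOXA10, HOXA11 and HOXA13 in A673 only, and H3K27ac in both CHLA10 libraries lies at genes of the B, C and D clusters.

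The third comparison took H3K27ac regions over 2.5 kb from gene boundaries, the candidates for enhancers. Of 94784 merged regions, 4109 were marked in A673 only, 8176 in CHLA10 only and 2467 in all 4 libraries, against 1327 and 1196 for the 2 mixed splits. The 3 strongest A673-only regions lay on the short arm of chromosome 21 (8221906 to 8244297, 8450845 to 8472136 and 8404870 to 8427333), 392 to 621 kb from LOC102723475. They were 21292 to 22464 bp long, far above the median of A673-only regions (920 bp). Distances were taken to protein-coding genes only, and whether reads map uniquely there was not checked, so these 3 are not read as enhancers. Then came a region inside LETM2, a mitochondrial protein gene, and one 15.5 kb from ARSA, the arylsulfatase A gene. In CHLA10 they lay inside TPRG1, ITPKB, a signalling kinase gene, DLG2, a synaptic scaffold gene, and PALM2AKAP2, and 68.5 kb from LRATD2. The DLG2 region (chromosome 11, 84161399 to 84165643) held a CHLA10 HOXD13 peak. HOXD13 of CHLA10 lay in 6.05% (5.55 to 6.59) of CHLA10-only regions and 0.292% (0.151 to 0.510) of A673-only regions. For A673 HOXD13 the shares were 5.82% (5.12 to 6.58) of A673-only and 5.50% (5.02 to 6.02) of CHLA10-only regions. Regions marked in all 4 libraries held A673 HOXD13 in 21.5% and CHLA10 HOXD13 in 7.09%, and were longer (median 2039 bp, against 920 and 1038 bp). Counting 1 library for A673 in place of both turned the order of the lines, with 34935 A673-only and 9805 CHLA10-only regions without A673 replicate 1, and 27979 and 9381 without A673 replicate 2. Without CHLA10 replicate 1 there were 4981 and 13287, and without CHLA10 replicate 2 there were 4433 and 23719.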

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

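All tests of explanations here were chosen after the results they concern were seen. Signal in data that entered no comparison was counted on unplaced and unlocalised sequences, where the 9 A673 lists held 367 peaks and the 9 CHLA10 lists 254. HOXD13 peaks near gene boundaries came to 2.09 times the random level in A673 and 0.957 times in CHLA10. The CHLA10 share did not depart from random placement (interval 2.15% to 3.61%, random mean 2.94%). Its ratio was 1.08 with the upper 50% of each list by q. At gene boundaries only A673 thus departed from random, and the difference was not tested. The boundaries include both ends of each gene. H3K4me3, a promoter mark, lay at HOXD13 peaks above the random level in both lines (6.05 times in A673, 5.76 times in CHLA10). EWS-FLI1 activated genes with a HOXD13 peak came to 1.66 times the expected number in A673 and 0.745 times in CHLA10, a difference that was not tested either.

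Far fewer gene ends carried H3K27ac in A673 only (446) than in CHLA10 only (1678). Fewer A673 peaks would not account for it, since the A673 H3K27ac lists were the longer ones, with 40470 and 47393 peaks against 39740 and 24293 (the closest ratio 1.02). The need for a peak in both A673 libraries, which repeat each other poorly, is unlikely to be the whole reason. The higher of the single A673 libraries covered 22.97% of genes with H3K4me3 and the lower CHLA10 library 30.9%. These shares cannot bound the effect of poor repeat itself, since noise in a library can also lower its own coverage. Leaving out A673 replicate 1 or 2 gave 1667 against 2210 or 1428 against 2222 genes. Those counts ask 1 library of A673 and 2 of CHLA10, so they are not a like comparison. Housekeeping genes, which both lines need, were marked in both replicates at 5 genes in A673 and 17 in CHLA10, a difference of 12, so the A673 lists may miss acetylated gene ends in general. Replicates that fail to repeat each other also lower a count that needs both, so these counts cannot separate the 2 explanations. A difference between the lines themselves stays open and was not tested.

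Most HOXD13 peaks were called in 1 line. Peaks near the calling threshold of their own list are unlikely to be the whole reason. Even in the 10% with the highest −log10 q the interval for the shared part ended at 17.6% in A673 and 34.2% in CHLA10. A site just under the threshold of the other list also counts as unshared, and this ranking cannot detect that. Unequal selection of peaks before deposition cannot be told apart from a difference in binding, because A673 kept 9.90 times the share of peak numbers that CHLA10 kept and the peaks left out are not in the lists. CHLA10 H3K27ac exceeded A673 H3K27ac at shared sites too (51.1% against 19.3% of shared CHLA10 peaks), but from shared to CHLA10-only sites it fell less than A673 H3K27ac did, by a factor of at least 1.44, so binding that follows line-specific active chromatin is a hypothesis consistent with CHLA10-only sites, in 1 HOXD13 library per line. For A673-only sites it stays open. The same factor was at least 1.67, yet A673 HOXD13 lay in 5.82% of A673-only and 5.50% of CHLA10-only distal regions. A673 H3K27ac also covered these sites less often than CHLA10 H3K27ac did (18.3% and 14.9% against 25.2% and 20.0%). That order was not particular to HOXD13 sites. A673 H3K4me3 replicate 1 peaks showed it too (18.2% and 19.4% against 36.6% and 25.2%).

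Gene ends with H3K4me3 in CHLA10 and no A673 peak of any list within a stretch of at least 300 kb numbered 44, 17 of them on chromosome X, while the reverse count was 1. Fewer A673 peaks overall do not account for it, since A673 had 341335 peaks and CHLA10 239454, a ratio of 1.43. Longer H3K27me3 lists in CHLA10 may explain the low reverse count on the autosomes, where leaving out the H3K27me3 lists gave 29 and 42 (a ratio of 0.690), but not on chromosome X, where the counts were 17 and 0 with or without them, a difference of 17. CDKN2A and CDKN2B, cell cycle inhibitor genes often lost in tumours, are among the 44: they held 0 A673 peaks, in an empty stretch of 542 kb (chromosome 9, 21903877 to 22446269), and 7 CHLA10 peaks, all H3K4me3. Loss of DNA in A673 cannot be told apart from chromatin without these marks, because the lists hold no read counts outside peaks.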

How the results depend on the processing

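The use of only the boundary with more H3K4me3 libraries, the removal of genes in long stretches free of peaks, and leaving out replicates for the gene lists were chosen after the results were seen; the other alternatives were planned. Of 1740 values recomputed under an alternative, 1574 kept their direction, their side of the threshold or their size, 146 moved, 14 passed a threshold they had missed, 2 lost it and 4 reversed. Secondary gene-list counts, all of which had missed the threshold, made up 1086 of these values, and 1079 of them missed it again. The other 7 passed and are not named below. The total therefore says little about the other results. All 24 replicate overlaps moved, as did 35 of 56 shares of marks at HOXD13 peaks. For those shares, leaving out 1 of 2 libraries cannot move a value beyond the SD. No paired analysis was possible because the labels share replicate numbers 1 and 2 across groups without stating a shared culture or day, and the results are counts of peak presence with no test. The motif alternatives were not run, since the motif search itself was not. Unless an alternative changes the number of peaks or genes by its own construction, the cause was not tested. Unknown read depth limits every comparison: a missing peak is not an absent mark.

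The share of A673 HOXD13 peaks found in CHLA10, 7.22%, was 5.17% with the upper 50% of each list by q and 10.4% with lists of equal peak number; that of CHLA10 peaks, 24.0%, was 17.6% and 10.5%. At gene boundaries lay 8.97% of A673 and 5.34% of CHLA10 peaks with a window of 2.5 kb. For A673 that share was 4.92% with the upper 50% and 4.34% with equal number. The CHLA10 share over random placement, 0.957, turned to 1.08 with the upper 50%.

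Marks at HOXD13 peaks moved in size in A673 and CHLA10. An overlap of at least 50% of the smaller peak gave 8.10% and 6.65% for H3K4me3, 13.4% and 36.5% for H3K27ac, and 30.7% and 6.29% for H3K4me1. The upper 50% gave 3.92% and 2.43%, 11.2% and 30.3%, 28.3% and 5.24% for the same marks, and 0.191% for H3K27me3 in CHLA10. Equal number gave 6.19% and 6.81% for H3K4me3, 11.9% and 42.2% for H3K27ac, 21.9% for H3K4me1 in A673 and 4.48% for H3K27me3 in A673. A peak in both replicates of the mark gave 7.57% and 6.48%, 9.66% and 36.4%, 24.8% and 2.81%, and 2.5% and 0.143% for H3K4me3, H3K27ac, H3K4me1 and H3K27me3. A peak in either gave 10.2% and 11.96%, 23.7% and 58.4%, 46.9% and 13.2%, and 4.33% and 0.619%. H3K27ac stayed higher in CHLA10 and H3K4me1 higher in A673 under each of these alternatives.

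Replicate overlap, as a share of the shorter list, is given for overlap of at least 50%, the upper 50% and equal number in turn. In A673 it was 89.8%, 93.7% and 90.2% for H3K4me3, 21.3%, 30.4% and 27.4% for H3K27ac, 59.5%, 75.6% and 55.1% for H3K4me1, and 77.1%, 75.4% and 76.0% for H3K27me3. In CHLA10 it was 82.1%, 93.9% and 89.8%, then 67.7%, 73.5% and 60.1%, then 21.9%, 20.1% and 23.4%, and 60.5%, 61.1% and 63.7%.

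Counts of genes marked in A673 only and CHLA10 only rose with all annotated genes, a larger set by construction: 748 and 852 for H3K4me3, 956 and 2736 for H3K27ac, 3420 and 168 for H3K4me1, and 2118 and 2130 for H3K27me3, where the ratio of CHLA10-only to A673-only genes turned from 0.782 to 1.01. For H3K4me3 the upper 50% gave 1323 in CHLA10 only, and the ratio turned from 1.01 to 0.972 with a window of 500 bp and to 0.658 with equal number. H3K27ac in A673 only was 1031 with a window of 2.5 kb and 290 with 500 bp. H3K4me1 in A673 only was 3012 and 985 with these windows, 980 with the upper 50% and 590 with equal number. H3K4me1 in CHLA10 only was 101 with 2.5 kb, 29 with the upper 50%, 113 with equal number and 28 at the boundary with more H3K4me3 libraries. Leaving out 1 replicate gave 502 to 1667 genes for H3K27ac in A673 only, 2085 to 3395 for H3K27ac in CHLA10 only, 1676 to 4492 for H3K4me1 in A673 only and 68 to 308 for H3K4me1 in CHLA10 only. Distal H3K27ac regions came to 4433 to 34935 in A673 only and 9381 to 23719 in CHLA10 only, and without A673 replicate 1 or 2 the A673-only regions were the more numerous (34935 against 9805 and 27979 against 9381). These counts rise by construction when 1 library stands for a line. Distal regions in CHLA10 only were 4349 with the upper 50%. The mean share of A673 H3K4me3 gene ends with H3K27ac, 22%, was 35.7% with 2.5 kb, 15.6% with 500 bp, 17.1% with the upper 50%, 15.4% with equal number and 15.7% at the boundary with more H3K4me3 libraries. With the upper 50%, bivalent genes fell to 215 in A673 and 69 in CHLA10, and A673 ends with neither mark rose to 8111.

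Among gene lists, the EWS-FLI1 repressed genes in A673 lost their call with the upper 50% (12 genes, 5.02 expected, adjusted permutation p = 0.0748) and with equal number (7, 3.24 expected, adjusted permutation p = 0.394), although the ratio to the expected number, 2.08 with all peaks, was 2.39 and 2.16. With a HOXD13 peak inside the gene or within 10 kb, HOX (8 genes), mesenchymal (17) and EWS-FLI1 activated genes (13) passed in A673. That alternative matched random lists on gene length and let 1 peak count for several neighbouring genes. For H3K4me3 in A673 only, developmental transcription factor genes passed with the upper 50% (12 genes). Leaving out 1 replicate gave 7 to 10 of these and 4 to 6 neural genes; the developmental list passed without A673 replicate 2 and without CHLA10 replicate 1, and the neural list without CHLA10 replicate 1.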

Other observations

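Shares of the covered length are described here for autosomes only. Among these, chromosome 13 had the H3K27me3 shares furthest apart by ratio (0.1302). It held 2.58% ± 0.0206 (SD, n = 2) of the H3K27me3 length in A673 and 0.336% ± 0.0756 in CHLA10, with H3K4me3 shares of 2.12% ± 0.00271 and 1.79% ± 0.00334. The H3K4me1 shares were 2.43% in A673 and 0.923% in CHLA10, and those of H3K27ac 2.09% and 1.45%, so all 4 marks were lower in CHLA10 there. HOXD13 peaks on chromosome 13 made up 2.67% of the A673 list and 0.715% of the CHLA10 list.

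H3K27ac and H3K4me1 also fell on different chromosomes. Chromosome 19, where SUGP1, MAU2, NTF4, KCNA7 and RAB3D lie, held 5.35% ± 0.219 (SD, n = 2) of the H3K27ac length in A673 and 2.101% ± 0.0745 in CHLA10, against 5.71% ± 0.0239 and 5.68% ± 0.0185 for H3K4me3. Chromosome 4 held 2.71% ± 0.0322 and 5.89% ± 0.0459 of the H3K27ac length, against 3.89% ± 0.00823 and 4.56% ± 0.0256 for H3K4me3. Both were the extremes by H3K27ac ratio among autosomes, and other autosomes shifted too. CHLA10 over A673 was 0.464 on chromosome 16 and 0.596 on chromosome 20, and 1.35 on chromosome 3. H3K4me1 shifted in the same directions as H3K27ac, with 2.26% of its length in A673 and 0.996% in CHLA10 on chromosome 19, and 3.53% and 7.01% on chromosome 4. For HOXD13, chromosome 4 held 5.52% of A673 and 9.24% of CHLA10 peaks. No explanation of these shares was tested.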
